A study of Mus musculus with 6 samples.

How the data were processed

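RNA sequencing was performed on colonic ILC2s sorted from mice given water or 3% DSS for 6 days, with 3 libraries in each of 2 groups. Per the labels' protocols, RNA was extracted with TRIzol, full-length cDNA was made with a SMART-Seq HT kit, and paired-end libraries were made with a Nextera XT kit, which does not mark the strand. Cutadapt 1.9 and HISAT2 2.2.1 with the mouse build mm10 are named per the submitters' processing notes; the counting tool, the annotation and the gene lengths are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments scaled by gene length and library depth) for 23268 genes by symbol. Each sample was placed in its group by its title, and its column by its name.

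Within each gene the deposited FPKM values were whole multiples of a common step. Whole fragments (tolerance 0.001) were recovered for 22701 of 22701 genes above 0, or 100.0%, and gave depths of 9962415 to 23119390 fragments per library; FPKM of a gene near 1 therefore rests on few fragments, most so in DSS replicate 3. A gene above 0 in only 1 library meets this tolerance whatever its value, so the 100.0% is partly fixed in advance. In simulated data, 98.4% of 4631 genes above 0 in all libraries were recovered exactly. Genes at 0 in some library, as S100a8, Wfdc17 and Retnlg are here, were not scored. Because the unit is FPKM, no count model was used for the main result; limma voom on the recovered fragments was an added alternative. Chi-square values between libraries were far above sampling noise, so no library was treated as a duplicate.

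Gene symbols were matched to GENCODE M21 (build GRCm38, the same as mm10) for coordinates, overlaps, lengths and GC content: 21332 matched by symbol, 392 through older or newer symbols, and 1544 had no single match, Garin1a among the named genes. Coordinates are 1-based.

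Before the data were examined, the samples, the main test, the gene lists, the rule for named genes and most other settings were fixed. The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1) for genes with a mean FPKM of at least 1 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 5 expressed members were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the 27 lists tested, with an estimated correlation and fry as alternatives. The list of mitochondrially encoded genes had no member among the genes used here. Named genes were the 12 largest changes in each direction among those that passed with separated groups, leaving out predicted genes, pseudogenes and antigen receptor segments, then the highest statistics where fewer than 12 passed; up to 4 members of each list with the smallest p; and 14 ILC2 and leukocyte genes whatever their result. The text gives only some of the list members that this rule names, chosen after their values were seen, and the others are not reported here. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15 and pandas 2.3.3.

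Same-numbered control and DSS libraries deviated together from their group means, with correlations of 0.189, 0.262 and 0.545 for replicates 1, 2 and 3, so by the rule used here (each above 0.1) the numbers were taken to pair the samples. This pairing comes from the data, not the labels. Among genes with a mean FPKM of at least 5 the correlations were 0.141, 0.035 and 0.25. Control replicate 1 correlated more with DSS replicate 2 (0.345), and control replicate 2 had 0.101 with DSS replicate 1. Replicates 1 and 2 paired the other way round thus meet the same rule, so it cannot show which libraries belong together. The main test has no block, and blocked values are given where they change a call.

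The test was checked on fragments simulated for the real genes with 200 genes changed. With a spread as in the real libraries, 51.8% of 85 tested genes changed 4-fold and 11.1% of 90 changed 2-fold were recovered among 11500 genes, and 5 unchanged genes were called. With an even spread, these were 97.5% of 80 and 41.9% of 86 among 11323 genes, with 15 unchanged genes called. A list of 21 genes shifted 2-fold was called in both, and of 26 unshifted lists 1 was called with the even spread and 0 with the real spread. Each gene was simulated independently, so these list counts do not show how the list test behaves where genes vary together. In the real libraries the estimated inter-gene correlation reached 0.82, for cytosolic ribosomal proteins.

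Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at a mean FPKM of 5, rescaling to an equal total, median-of-ratios and quantile normalization, no trend, robust estimation, library weights, the replicate block, a minimum change of 1 on the log2 scale, an adjusted p under 0.1, and leaving out each library. Leaving out both replicates 3, voom, library weights with the gene-by-gene update, and list tests with pseudocount 5, no filter, rescaling, quantile normalization, no trend, robust estimation and library weights were chosen after seeing the data.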

Results

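Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes known for making type 2 cytokines without an antigen receptor. They were sorted from the colon of C57BL/6 mice aged 6 to 8 weeks that had drunk water (control) or 3% dextran sulfate sodium (DSS) for 6 days. DSS is a chemical that injures the colonic epithelium and causes colitis. Gene expression was measured by RNA sequencing of full-length cDNA in 3 control and 3 DSS libraries, as FPKM values for 23268 genes. The comparison asks which transcripts of colonic ILC2s differ between DSS colitis and water controls. The whole fragments behind the values numbered 23119390, 17546966 and 12670662 in control replicates 1, 2 and 3. They numbered 14849084, 18951020 and 9962415 in DSS replicates 1, 2 and 3. The labels do not say whether each library came from its own mouse or from a pool, so p-values measure the spread between these samples, which may be technical. Levels below are mean FPKM ± SD with n = 3 libraries per group, control first. Log2 changes are DSS minus control on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

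The libraries did not group by treatment alone. The first principal component held 48.1% of the variance and set DSS replicate 3 (score 70.48) and control replicate 3 (28.31) apart from the other 4 libraries (−33.03 to −10.87). The second held 28.5% and set DSS replicate 1 apart (−57.93). Olfactory receptor genes, which lymphocytes are not known to use, had a mean FPKM of 0.962 in DSS replicate 3 and 0.583 in control replicate 3. In the other 4 libraries it was 0.034 to 0.182. Cytosolic ribosomal protein transcripts took 12.49% of the fragments of DSS replicate 1 and 5.97% to 8.47% of those of the other 5. Pearson correlations of log2 values between libraries ran from 0.8988 to 0.9802.

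Of 12187 genes tested, 27 differed between the groups at a limma adjusted p under 0.05, 9 higher and 18 lower in DSS. For each of the 27, the 3 DSS libraries lay entirely on one side of the 3 control libraries. Among the 27, the largest rises were in genes known from neutrophils and other myeloid cells. S100a9 and S100a8 encode the subunits of the antimicrobial protein calprotectin. S100a9 rose from 1.05 ± 0.426 to 40.8 ± 4.10 FPKM (log2 change 4.37 ± 0.23 SE, limma adjusted p = 8.45e-05). S100a8 rose from 0.580 ± 0.654 to 28.1 ± 4.08 (4.27 ± 0.32 SE, limma adjusted p = 8.56e-04). Wfdc17, which encodes a small whey acidic protein family member, rose from 0.453 ± 0.440 to 22.0 ± 6.50. Il1b, which encodes the inflammatory cytokine IL-1β, rose from 2.11 ± 0.485 to 20.9 ± 6.25. Retnlg, a resistin-like gene, rose from 0.556 ± 0.512 to 11.95 ± 6.56. S100a8, Wfdc17 and Retnlg each had 0 fragments in at least 1 control library. Among abundant transcripts, the small heat shock protein gene Hspb1 rose from 206 ± 3.27 to 1120 ± 539. The HSP40 co-chaperone gene Dnajb1 rose from 906 ± 121 to 2607 ± 376, and Ltb, which encodes lymphotoxin β, from 111 ± 6.94 to 255 ± 17.5. Mir142, a microRNA hairpin locus on chromosome 11 (mm10, 87756864 to 87756927), rose from 31.0 ± 8.80 to 100.3 ± 20.2. It shares its position with Mir142b on the opposite strand, and its fragments cannot be told from those of a longer transcript across it. Iigp1 (limma adjusted p = 0.0912), Cab39l and Slpi (both 0.0984) had the next highest statistics and did not pass.

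Il5, which encodes the eosinophil growth factor IL-5, had the largest fall of the 27 on the log2(FPKM + 1) scale. Its mean went from 359 ± 11.5 to 66.0 ± 7.50 FPKM, 5.44-fold lower (log2 change −2.43 ± 0.19 SE, limma adjusted p = 8.66e-04, lower in 3 of 3 DSS libraries). It lies on chromosome 11 (mm10, 53720794 to 53725106) and shares 417 bp with the antisense gene Gm12214, from which these unstranded libraries cannot separate it. Irf4, a transcription factor of activated lymphocytes, fell from 21.8 ± 2.35 to 6.15 ± 0.752. Gprc5a, an orphan G protein-coupled receptor gene, fell from 15.8 ± 2.30 to 2.74 ± 1.45, a larger ratio of means (5.79-fold) than that of Il5. Garin1a fell from 97.3 ± 19.8 to 23.2 ± 6.17 and Abhd17c from 113 ± 12.4 to 34.9 ± 5.65. The chemokine receptor gene Ccr4 fell from 155 ± 4.06 to 55.9 ± 10.7 and Ccr7 from 167 ± 13.7 to 58.7 ± 14.5. Tnfrsf1b, which encodes TNF receptor 2, fell from 108 ± 10.8 to 37.0 ± 9.17. Ptgs2, the inducible prostaglandin synthase gene, fell from 88.6 ± 13.8 to 31.0 ± 6.33. Tiparp, a target of the aryl hydrocarbon receptor, fell from 320 ± 55.3 to 115 ± 8.82. Rem2 and Stab2 completed the 12 largest falls, with log2 changes of −1.60 and −1.51. Stab2 and Tiparp also share sequence with antisense genes.

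The number of changed genes depended on single libraries. It was 4, 5 and 6 without control replicates 1, 2 and 3, and 413, 7 and 19 without DSS replicates 1, 2 and 3. The 4 genes S100a8, S100a9, Wfdc17 and Il5 passed in each of these 6 fits. With voom on the recovered fragments, 10 of the 27 no longer passed. Among these were S100a9, S100a8 and Wfdc17 (limma adjusted p = 0.0703, 0.145 and 0.178), while Il5 passed. For S100a9, S100a8 and Wfdc17 the log2 changes were larger there, with wider errors: 5.33 ± 0.958 SE, 5.97 ± 1.38 SE and 6.13 ± 1.53 SE, against 4.37, 4.27 and 3.996. Without both replicates 3, 5 genes passed, all higher in DSS, and Il5 had a limma adjusted p of 0.0645, the highest of a range from 1.80e-09 over all its settings. With the replicate number as a block, 22 genes passed, 12 higher and 10 lower in DSS, and 13 of them were among the 27. Mir142, Dnajb1, Ltb, Ccr4, Ccr7, Ptgs2, Stab2 and Tiparp no longer passed with the block. After median-of-ratios scaling 9 genes passed, 5 higher and 4 lower.

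**Figure D1:**
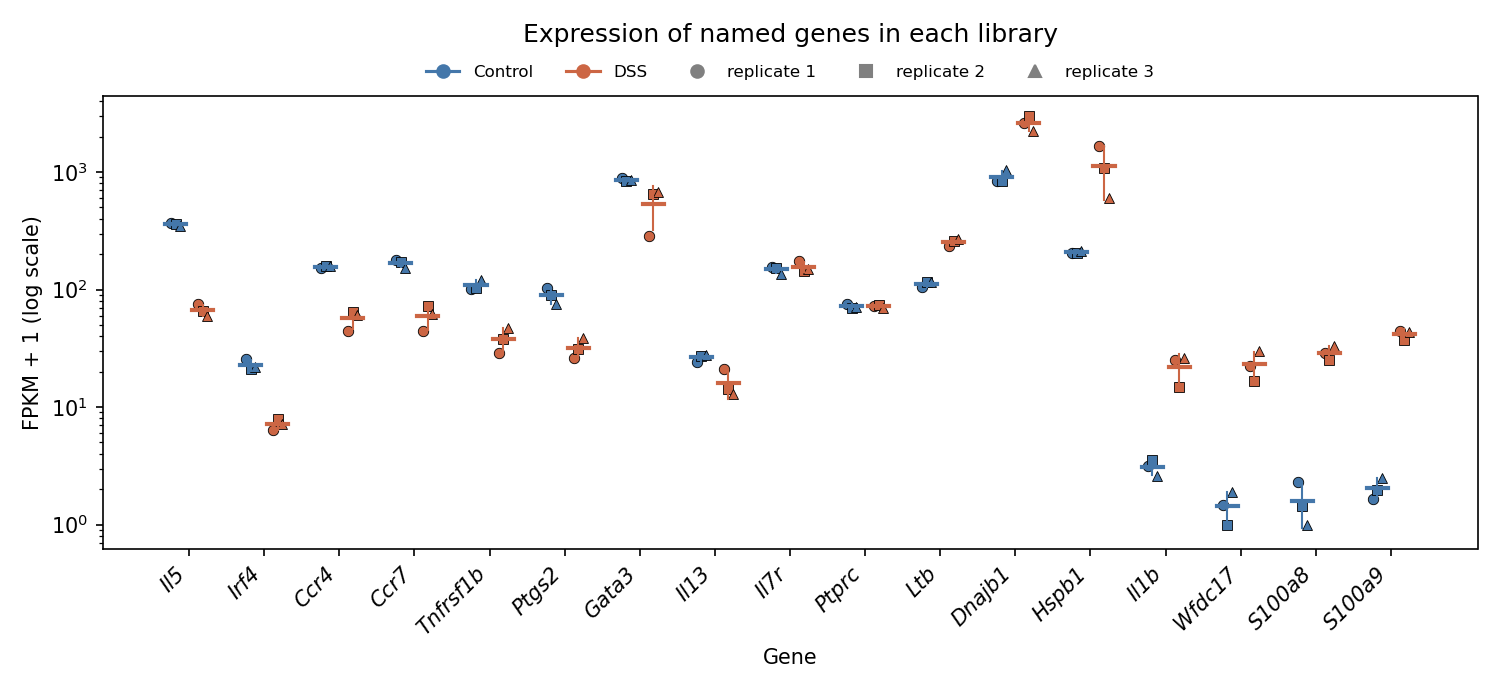
FPKM + 1 on a log axis for 17 named genes in each of the 3 control (blue) and 3 DSS (orange) libraries, with symbols for the replicate number, horizontal bars for the group mean and vertical lines for ± 1 SD. Mean Il5 was 359 FPKM in control and 66.0 in DSS without overlap, while Ptprc (71.3 ± 3.27 and 70.8 ± 1.64) and Il7r (148 ± 11.1 and 155 ± 15.7) overlapped.

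Gene lists fixed beforehand were then compared with all other genes. With a preset inter-gene correlation of 0.01, 19 of 27 lists passed camera, 8 higher and 11 lower in DSS. None passed camera when the correlation was estimated from the data (lowest adjusted p = 0.1153). By fry, which tests whether a list's genes move one way on balance, 9 passed. The 10 of the 19 that did not (fry adjusted p = 0.0711 to 0.716) were the ILC2 effector, interferon, NF-kB, STAT, cell cycle, glycolysis, neuropeptide, circadian, ILC1 and NK, and ribosomal lists. The camera calls below therefore hold only under the preset setting. A higher correlation is not what ended all of them. For the MHC class I, co-stimulatory, trafficking and macrophage lists the estimate was below 0.01 (−0.0046, −0.0176, 0.0011 and −0.0935). Their unadjusted camera p still rose, from 0.0150, 3.17e-04, 0.0109 and 1.11e-03 to 0.0617, 0.0178, 0.0520 and 0.0287. Passing fry too were the ILC2 identity, cholesterol, co-stimulatory, trafficking, MHC class I, MHC class II, macrophage, neutrophil and epithelial lists. The fry adjusted p of these 9 was 0.0280 to 0.0454.

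Transcripts that define ILC2s were lower as a group. Of 21 tested ILC2 identity factors and receptors, 18 had a lower value in DSS, and 11 of them had no overlap between the groups. Of all 12187 tested genes, 1170 had every DSS library below every control library and 774 had them above. These are the shares to set beside such counts here and below. The list fell with a median log2 change of −0.51 (camera adjusted p = 3.26e-07, adjusted p = 0.1153 with an estimated correlation). In the same libraries the neutrophil, macrophage and epithelial lists rose (medians 1.16, 0.93 and 0.84), while the T cell, stromal and ILC3 lists did not (−0.11, −0.02 and −0.20). Over all genes 0 members passed, and 4 were lower adjusted over the list alone. Nfil3, a transcription factor needed for innate lymphoid cell development, measured 255 ± 3.46 and 114 ± 19.3. Rora, a nuclear receptor required for ILC2s, measured 154 ± 16.7 and 78.3 ± 15.9. Icos measured 293 ± 10.5 and 163 ± 27.9, and Il2ra 109 ± 1.27 and 66.8 ± 4.64. Gata3, the master regulator of ILC2s, measured 859 ± 22.8 and 538 ± 217 (limma adjusted p = 0.497), with its lowest value, 287, in DSS replicate 1. The receptor genes Il1rl1 (54.8 ± 7.68 and 44.6 ± 3.65), Il17rb (255 ± 12.6 and 307 ± 56.5) and Klrg1 (266 ± 10.96 and 222 ± 73.9) overlapped between the groups. The Klrg1 log2 change of −0.31 depended on single libraries. Without 1 library it ran from −0.56 to −0.15, with a lowest limma adjusted p of 0.0295. Il7r and the leukocyte gene Ptprc overlapped too, and their log2 changes of 0.07 and −0.01 changed sign with the setting.

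The ILC2 effector molecules fell as well, with 12 of 17 lower and a median log2 change of −0.53 (camera adjusted p = 2.99e-05, adjusted p = 0.288 with an estimated correlation). Il5 was the 1 member that passed over all genes, and 6 were lower adjusted over the list alone. The values were uneven across cytokines. Il13 measured 25.6 ± 1.91 and 15.1 ± 4.46. Il9 measured 8.60 ± 0.434 and 1.116 ± 1.120 (limma adjusted p = 0.0763, or 0.0479 with the replicate block). Csf2, the GM-CSF gene, measured 5949 ± 599 and 3527 ± 1765. Arg1, which encodes the arginine-degrading enzyme arginase 1, measured 183 ± 21.5 and 117 ± 8.79. Tph1, the serotonin-synthesis enzyme gene, measured 7.60 ± 2.22 and 1.69 ± 0.121. Il4 (729 ± 39.2 and 651 ± 328), Il10 (2.27 ± 1.38 and 2.41 ± 1.25) and the epithelial growth factor gene Areg (1071 ± 85.3 and 1045 ± 247) overlapped.

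Cholesterol biosynthesis and uptake had the smallest list p by camera with the preset correlation. By fry or with an estimated correlation, other lists had a smaller unadjusted p. Of its 19 members 17 were lower in DSS, 11 with no overlap between the groups. The median log2 change was −0.68 (camera adjusted p = 6.86e-09, adjusted p = 0.1153 with an estimated correlation), with 0 passing over all genes and 7 lower adjusted over the list alone. Cyp51 and Hmgcs1, which encode sterol pathway enzymes, measured 129 ± 9.95 and 69.8 ± 7.79, and 20.3 ± 1.63 and 10.7 ± 2.16. Fdps measured 39.2 ± 4.99 and 20.2 ± 6.54, and Mvk, the mevalonate kinase gene, 12.4 ± 4.04 and 5.87 ± 1.06. Glycolysis and hypoxia genes also fell, with 17 of 21 lower and a median of −0.27 (camera adjusted p = 1.03e-04, adjusted p = 0.232 with an estimated correlation). Without DSS replicate 3 the median was −0.41. Over all genes 0 of these passed, and 2 were lower adjusted over the list alone. Hk2, the inducible hexokinase gene, measured 20.9 ± 1.57 and 9.75 ± 1.06, and Pkm 382 ± 28.3 and 223 ± 66.1. The cell cycle list fell, with 17 of 27 lower and a median of −0.23 (camera adjusted p = 8.70e-03, adjusted p = 0.456 with an estimated correlation). It had 0 members passing over all genes or adjusted over the list alone. Its leading members were helicase genes of DNA replication, with Mcm6 at 12.1 ± 3.42 and 5.89 ± 0.933 and Mcm3 at 14.7 ± 2.85 and 7.49 ± 2.57. The list did not pass without control replicate 1 (camera adjusted p = 0.0679) or DSS replicate 2 (0.09997). Its median was −0.40 without control replicate 2, and −0.15, −0.056 and −0.49 without DSS replicates 1, 2 and 3.

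Oxidative phosphorylation did not pass (camera adjusted p = 0.324), and its median (0.0011) differed in sign from its mean (−0.056) and its test. It passed downward without DSS replicate 1 (median −0.24, camera adjusted p = 2.75e-07) and upward without DSS replicate 3 (median 0.16, camera adjusted p = 0.0377). With no filter and with both kinds of library weights it also passed downward (camera adjusted p = 0.0256 to 0.0490). The lists for fatty acid handling (median −0.11), the unfolded protein response (−0.13) and apoptosis and p53 targets (−0.03) did not pass (camera adjusted p = 0.585, 0.281 and 0.570).

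Receptor and signalling genes gave further lists that fell, though some share members with the ILC2 identity list. Icos is also in the co-stimulatory list, and Nmur1 and Ptgdr2 are also in the neuropeptide list. Of the co-stimulatory and inhibitory receptors, 12 of 17 were lower, with a median of −0.31 (camera adjusted p = 9.50e-04, adjusted p = 0.1153 with an estimated correlation). Adjusted over the list alone, 1 was higher and 5 lower. The list did not pass with a mean FPKM of at least 5 (camera adjusted p = 0.0716), and its median was −0.65 without DSS replicate 3. Cd28 measured 131 ± 15.0 and 64.7 ± 18.8, and Tnfrsf9 99.8 ± 13.5 and 55.1 ± 14.3. Of the neuropeptide, lipid mediator and hormone receptors, 11 of 16 were lower, with a median of −0.41 (camera adjusted p = 8.88e-03, adjusted p = 0.340 with an estimated correlation). The prostaglandin E2 receptor gene Ptger2 measured 25.6 ± 3.38 and 12.8 ± 4.65, and the neuromedin U receptor gene Nmur1 86.5 ± 5.61 and 57.8 ± 13.0. Neither passed over all genes, and 0 passed adjusted over the list alone. This list did not pass with a mean FPKM of at least 5, after quantile normalization or with library weights (camera adjusted p = 0.201, 0.0504 and 0.0596). The NF-kB and TNF response list went both ways, with 13 of 20 lower and a median of −0.36 (camera adjusted p = 7.30e-03, adjusted p = 0.232 with an estimated correlation). Adjusted over the list alone, 2 members were higher and 4 lower. Cd83 measured 243 ± 9.56 and 76.9 ± 35.5, Rel 36.3 ± 4.68 and 19.6 ± 2.49, and the chemokine gene Ccl4 14.1 ± 4.12 and 39.3 ± 24.7. The same 3 settings ended this call (camera adjusted p = 0.126, 0.0741 and 0.0583), and the median was −0.19 without DSS replicate 1.

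In the trafficking list 12 of 19 members were lower, with a median of −0.16 (camera adjusted p = 0.0183, adjusted p = 0.175 with an estimated correlation). Ccr4 and Ccr7 passed over all genes, and 1 member was higher and 4 lower adjusted over the list alone. The chemokine receptor gene Cxcr6 measured 589 ± 23.3 and 298 ± 31.0. Klf2, a transcription factor of lymphocyte egress, measured 105 ± 12.6 and 219.8 ± 38.2. This list did not pass without control replicate 2 or DSS replicate 3 (camera adjusted p = 0.0569 and 0.156), nor in 4 other settings (0.0601 to 0.129). Its median was −0.27, −0.25 and −0.25 without DSS replicates 1, 2 and 3. The circadian clock list fell, with 12 of 14 lower and a median of −0.27 (camera adjusted p = 3.10e-03, adjusted p = 0.440 with an estimated correlation). Hlf measured 24.9 ± 1.80 and 12.6 ± 1.88, and Nr1d1 104 ± 13.6 and 50.4 ± 19.1, and 3 members were lower adjusted over the list alone. The circadian median was −0.0024, −0.42 and −0.56 without DSS replicates 1, 2 and 3. STAT-induced feedback genes fell, with 9 of 10 lower and a median of −0.33 (camera adjusted p = 0.0437, adjusted p = 0.456 with an estimated correlation). Socs2 measured 331 ± 33.4 and 198 ± 20.9, and the survival gene Bcl2 19.7 ± 1.23 and 36.3 ± 2.17, and 1 member was higher and 1 lower adjusted over the list alone. Without control replicates 1 or 2 or DSS replicates 1 or 3 the list did not pass (camera adjusted p = 0.110, 0.124, 0.1996 and 0.191), nor did it in 7 other settings (0.0550 to 0.603). Its median was −0.15 without DSS replicate 1. The immediate early and heat shock list did not pass, with 13 of 21 higher and a median of 0.05 (camera adjusted p = 0.173), although Dnajb1 passed by itself. It passed without DSS replicate 1 (median 0.26, camera adjusted p = 4.39e-03), with a mean FPKM of at least 5 (0.0147) and with both kinds of library weights (1.35e-03 and 3.31e-03). Nr4a2 measured 138 ± 3.19 and 50.3 ± 19.5.

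Antigen presentation and interferon genes were higher in DSS. All 7 MHC class II genes were higher, 4 with no overlap between the groups, with a median of 0.66 (camera adjusted p = 5.69e-05, adjusted p = 0.1153 with an estimated correlation). Over all genes 0 passed, and 3 were higher adjusted over the list alone. H2-Ab1 measured 77.0 ± 8.65 and 132 ± 7.94, and the invariant chain gene Cd74 322 ± 34.6 and 524 ± 113. Markers of cells that carry these molecules went both ways. The median was 0.93 for macrophages and monocytes (0.31 over all 14 members with no filter). It was 1.68 for the 4 expressed B and plasma cell genes, none of which passed, and 0.12 over all 9 with no filter. All genes had a median of 0.123 with no filter. The 4 expressed dendritic cell genes had a median of −0.54, 2 higher and 2 lower, with Xcr1 and Zbtb46 lower in every DSS library than in any control library. The interferon response list rose, with 18 of 26 higher and a median of 0.36 (camera adjusted p = 5.69e-05, adjusted p = 0.340 with an estimated correlation). The interferon-inducible GTPase genes Iigp1 and Irgm1 measured 14.3 ± 6.02 and 40.3 ± 1.32, and 27.8 ± 5.93 and 52.6 ± 2.40. Over all genes 0 members of this list passed, and 3 were higher adjusted over the list alone. The list did not pass without control replicate 3 (median 0.24, camera adjusted p = 0.0604) or without both replicates 3 (median 0.17, camera adjusted p = 0.0995). MHC class I presentation rose, with 10 of 13 higher and a median of 0.35 (camera adjusted p = 0.0239, adjusted p = 0.185 with an estimated correlation). The immunoproteasome gene Psmb9 measured 41.7 ± 6.01 and 79.3 ± 32.5, and 0 members passed over all genes or adjusted over the list alone. The list did not pass with the replicate block (camera adjusted p = 0.0648) or without control replicate 3 (0.315) or DSS replicate 2 (0.127). It did not pass with no filter, after median-of-ratios scaling or without both replicates 3 either (0.160, 0.101 and 0.117), and its median was 0.21 without DSS replicate 1.

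Markers of other cell types that a colonic sort could hold also differed. The neutrophil list rose, with 6 of 7 tested members higher and a median of 1.16 (camera adjusted p = 4.74e-07, adjusted p = 0.1153 with an estimated correlation). S100a9, S100a8 and Retnlg passed over all genes, and 3 were higher adjusted over the list alone. Retnlg kept its call in only 6 of 20 other settings, against 19 of 20 for S100a9 and for S100a8. The neutrophil median depended on the filter and scale. It was 0.46 over all 13 members with no filter, 0.40 with pseudocount 5, 2.86 with pseudocount 0.1, 0.58 with library weights and 4.48 with voom. Without DSS replicate 3 it was 0.77. Epithelial markers rose, with 10 of 10 tested members higher and a median of 0.84 (camera adjusted p = 3.35e-05, adjusted p = 0.1153 with an estimated correlation). Over all 18 members with no filter the median was 0.67 (camera adjusted p = 6.01e-04). Epcam measured 9.03 ± 1.28 and 16.5 ± 2.57, Lgals4 12.1 ± 4.71 and 22.9 ± 3.17, and 3 were higher adjusted over the list alone. Macrophage and monocyte markers rose, with 5 of 6 higher and a median of 0.93 (camera adjusted p = 2.99e-03, adjusted p = 0.1153 with an estimated correlation). Over all 14 members with no filter the median was 0.31 (camera adjusted p = 0.0173), and with pseudocount 5 it was 0.43. Cd14 measured 2.60 ± 0.919 and 12.4 ± 5.52 and was the 1 member higher adjusted over the list alone. ILC1 and NK markers rose, with 10 of 12 higher and a median of 0.40 (camera adjusted p = 0.0328, adjusted p = 0.440 with an estimated correlation). Ccl5 measured 20.5 ± 0.975 and 66.6 ± 68.1, and 0 passed adjusted over the list alone. The list did not pass without control replicates 1 or 2 or DSS replicates 1 or 2 (camera adjusted p = 0.110, 0.0660, 0.317 and 0.0568), nor in 5 other settings (0.0526 to 0.0776). Its median was 0.24 without control replicate 1, and 0.17 and 0.63 without DSS replicates 1 and 3.

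ILC3 markers did not pass (median −0.20, camera adjusted p = 0.0561) but passed downward with the replicate block (0.0424). With pseudocount 5, no filter and rescaling to an equal total they passed too (0.0459, 2.18e-03 and 0.0274). They also passed downward without control replicate 1, DSS replicate 1 or DSS replicate 2 (camera adjusted p = 0.0304, 2.51e-03 and 0.0261). Ltb rose, while Il17f measured 55.3 ± 9.63 and 17.2 ± 10.8 and Kit 60.8 ± 2.89 and 30.9 ± 9.26. Adjusted over the list alone, 1 was higher and 4 lower. T cell and stromal markers did not pass (medians −0.11 and −0.02, camera adjusted p = 0.866 and 0.902). The B and plasma cell, dendritic cell, and mast cell, basophil and eosinophil lists had fewer than 5 members with a mean FPKM of at least 1, too few for the main list test. With no filter they were tested: B and plasma cell markers passed upward (9 members, median 0.12, camera adjusted p = 0.0145). The dendritic list and the mast cell, basophil and eosinophil list did not (0.927 and 0.0507). Over all 22701 genes with no filter the median log2 change was 0.123, so the median of the B and plasma cell list was no higher. The plasma cell genes Jchain and Mzb1 measured 13.6 ± 5.18 and 113 ± 74.0, and 2.77 ± 1.85 and 55.3 ± 47.2. The dendritic cell genes Xcr1 and Zbtb46 measured 6.36 ± 1.55 and 1.897 ± 0.967, and 9.21 ± 0.758 and 3.46 ± 1.92. The basophil gene Mcpt8 measured 0.303 ± 0.524 and 2.48 ± 0.584. Cytosolic ribosomal proteins, a sign of library quality, rose, with 67 of 82 higher and a median of 0.23 (camera adjusted p = 3.10e-03, adjusted p = 0.737 with an estimated correlation). They fell without DSS replicate 1 (median −0.08, camera adjusted p = 4.39e-03) and did not pass without control replicate 3 (0.130) or with no filter (0.161). Without DSS replicate 3 the median was 0.49.

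**Figure D2:**
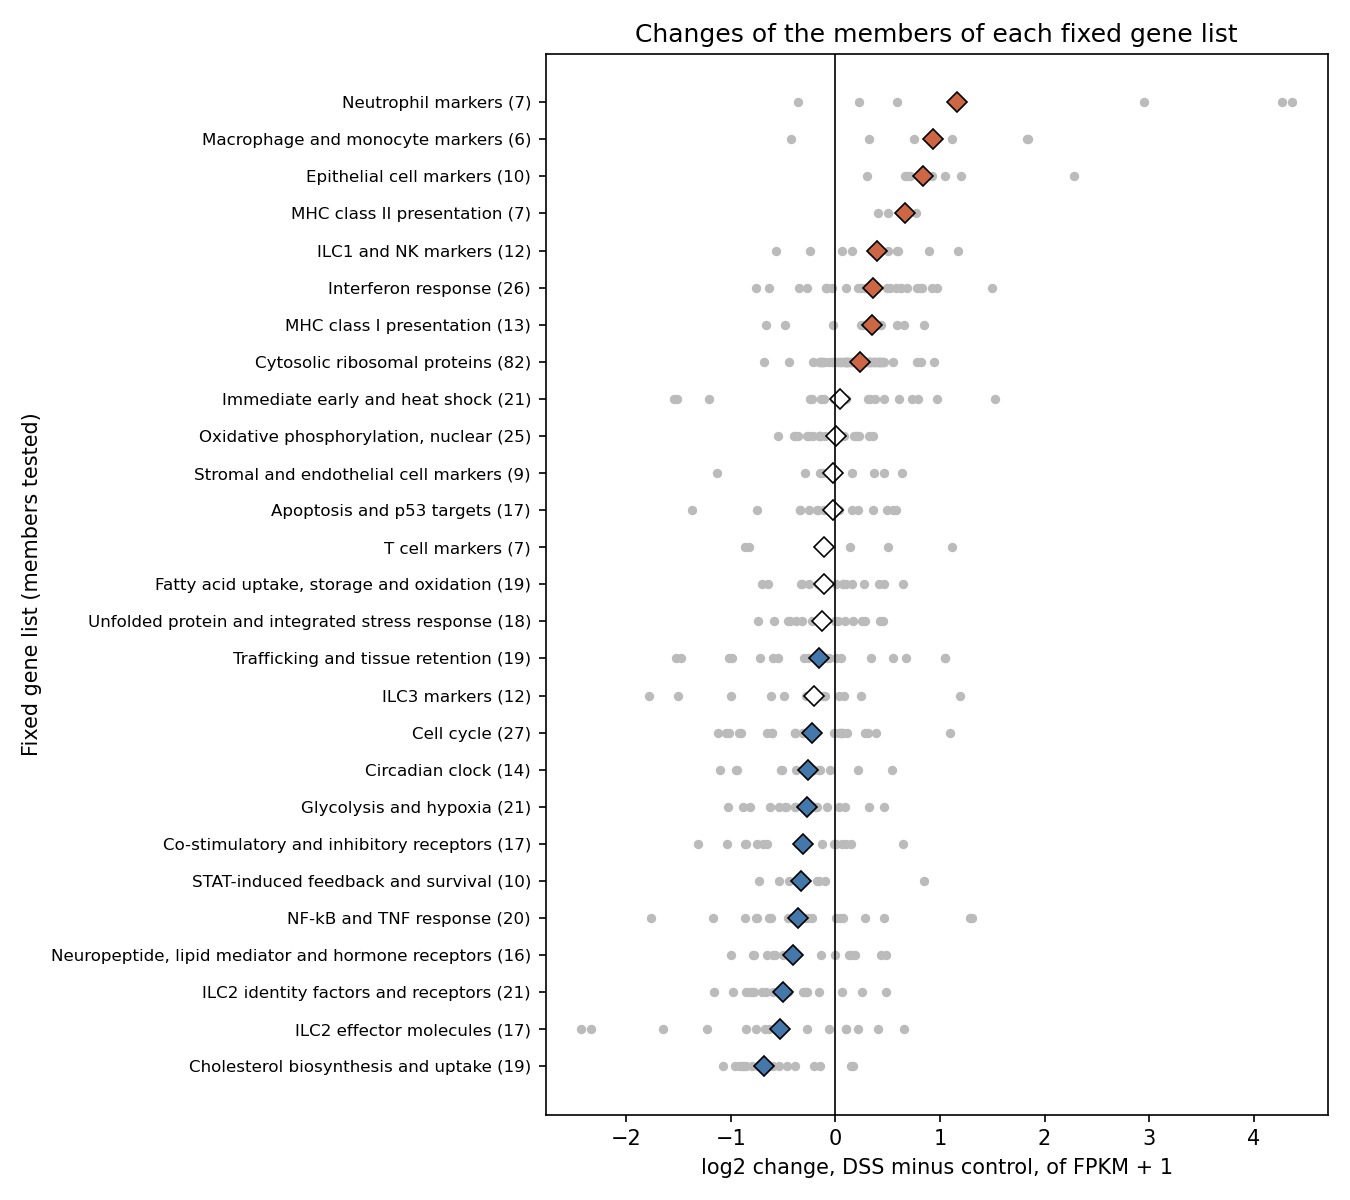
Log2 change (DSS minus control, of FPKM + 1) of each tested member (grey points) of the 27 fixed gene lists and the list median (diamonds), with the number of members tested in parentheses. Orange and blue diamonds mark lists higher and lower in DSS by camera with the preset correlation, white diamonds those that did not pass, and medians run from −0.68 for cholesterol biosynthesis to 1.16 for neutrophil markers.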

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

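Leaving out both replicates 3, voom, library weights with the gene-by-gene update, and list tests with pseudocount 5, no filter, rescaling, quantile normalization, no trend, robust estimation and library weights were chosen after seeing the data; the other settings were planned, and the cause of a change was not tested unless stated. The 27 changed genes (9 higher, 18 lower in DSS) became 14 after rescaling to an equal total (8 lower), 9 after median-of-ratios scaling (5 higher, 4 lower), 4 without the trend (3 higher, 1 lower), 5 without both replicates 3 (5 higher, 0 lower; fewer libraries), 53 at an adjusted p under 0.1 (18 higher, 35 lower), 635 with gene-by-gene library weights (251 higher, 384 lower) and 3286 with the default weights (1464 higher, 1822 lower), a fit that stopped before it converged. Higher genes were 4 with no filter and 3 with voom; lower genes were 11 after quantile normalization and 10 with the replicate block. Leaving out 1 library gave 4 to 413 genes, 3 to 132 higher and 1 to 281 lower, and 16 to 20 lists. With the block 22 genes (12 higher) and 19 lists passed; of the calls named it also changed Gcnt1, Cldnd1, Zfp954, Bpnt1, Serpinb1a and Cwc25, which were lost, beside those in the report, and it changed no other call among the named genes and lists. The 19 lists became 19 of 30 with no filter (B and plasma cell markers passed there), 11 of 22 with a mean FPKM of at least 5 (the epithelial, macrophage, neutrophil, stromal and T cell lists had too few members left), 9 by fry and 0 with an estimated correlation (limma camera; 1096 genes had an unadjusted p under 0.05 in the main comparison).

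Of 2936 comparisons of named genes with an alternative, 2462 kept direction and side of the threshold, 225 lost a call, 218 gained one and 31 changed sign, all among genes that did not pass. Only the 27 genes that passed could lose a call, so the 225 are not to be read against 2936. These 27 kept their call in 6 (Retnlg and Ltb) to 19 (Il5, S100a8, S100a9 and Wfdc17) of 20 settings. Log2 changes that changed sign were Cd79b −0.0032 after rescaling to an equal total; Ptprc 0.025 after median-of-ratios scaling; Il10 −0.070 and Ptprc 0.090 after quantile normalization; Cd8b1 −0.18, Cd3d −0.52, Cd79b −0.20, Batf3 −0.050, Il7r −0.068, Il10 −0.32 and Ptprc 0.026 with library weights; Cd3d −0.19, Cd79b −0.17, Il7r −0.041, Il10 −0.12 and Ptprc 0.013 with the gene-by-gene update; Il10 −0.021 with voom; and Dcn 0.031, Il4 0.044 and Areg 0.058 without both replicates 3. List medians whose test turned were immediate early and heat shock 0.047 with no filter, fatty acid handling −0.046 with library weights and −0.041 with the gene-by-gene update, the unfolded protein response −0.049 with library weights, stromal markers −0.027 with pseudocount 0.1, −0.080 after rescaling to an equal total, 0.24 with voom and 0.097 without both replicates 3, and oxidative phosphorylation 0.076 without both replicates 3. Medians of passing lists that moved by over 1.5 times were cell cycle −0.13 with pseudocount 5, −0.49 with a mean FPKM of at least 5 and −0.46 with library weights, −0.47 with voom and −0.39 without both replicates 3; glycolysis −0.17 after quantile normalization, −0.14 with library weights, −0.18 with the gene-by-gene update and −0.42 without both replicates 3; neuropeptide receptors −0.26 with pseudocount 5; co-stimulatory receptors −0.21 after quantile normalization; trafficking −0.078 with no filter and −0.067 with the gene-by-gene update; circadian −0.15 with pseudocount 5, −0.17 with the gene-by-gene update, −0.41 with voom and −0.52 without both replicates 3; ILC1 and NK markers 0.70 and ribosomal proteins 0.47 without both replicates 3 (ribosomal 0.13 after quantile normalization); macrophage markers 1.41 with pseudocount 0.1 and 1.40 with voom; and epithelial markers 1.40 with pseudocount 0.1, 0.39 with pseudocount 5, 1.26 with library weights and 1.895 with voom, beside those in the report. Over the fits without 1 library, log2 changes ran from −0.31 to 0.33 for Cd79b, −0.027 to 0.029 for Ptprc, −0.22 to 0.86 for Acta2, −0.32 to 0.42 for Il10, −0.32 to 1.09 for Cd3d, −0.014 to 0.12 for Il7r, −0.66 to 0.00014 for Il4 and −0.23 to 0.11 for Areg, and medians from −0.26 to 0.21 for T cell markers, −0.18 to 0.30 for stromal markers, −0.21 to 0.047 for fatty acid handling, −0.077 to 0.49 for ribosomal proteins, −0.24 to 0.16 for oxidative phosphorylation and −0.084 to −0.030 for apoptosis. With 9962415 fragments in the shallowest library, low FPKM values are limited by counting.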

Other observations

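The tests of ILC2 dilution, of scaling in DSS replicate 1 and of a general rise with members under a mean FPKM of 1, and the choices to count further neutrophil transcripts with no filter (a filter over both groups favours genes high in DSS) or by their control level, were made only after results, a filtered count among them, were seen. Some genes outside the fixed lists or the naming rule stood out and were chosen after their values were seen. Hsp90aa1, Hspd1 and Hspe1 had higher values in all 3 DSS libraries without passing limma, while the fixed immediate early and heat shock list did not pass (camera adjusted p = 0.173) and had 8 of 21 members lower: Hsp90aa1 measured 639, 603 and 707 FPKM in control replicates 1 to 3 and 1788, 1395 and 1135 in DSS replicates 1 to 3 (limma adjusted p = 0.132), Hspd1 96.4, 96.0 and 107 against 179, 205 and 166 (0.136), and Hspe1 370, 346 and 346 against 1754, 846 and 525 (0.222). Il3, a cytokine gene, measured 15.3, 3.59 and 4.09 in control and was listed at 0 in all 3 DSS libraries (limma adjusted p = 0.0906).

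Chance as the source of the counts was examined by regrouping. The real grouping gave 27 genes and the highest of the other 9 splits into 3 and 3 gave 0; for lists these were 19 and 13. In each case 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Of the 3 other splits that part all 3 same-numbered pairs, each gave 0 genes, and they gave 10, 2 and 7 lists. At an unadjusted p under 0.05 the real grouping gave 1096 genes, and 2 of the other 9 gave more, 1279 and 1103; both set control replicates 1 and 2 and 1 DSS library apart from a side holding both replicates 3.

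S100a9, S100a8 and Retnlg were higher in each DSS library than in every control library, although the cells were sorted as ILC2s; the markers of the sort are not given. A general rise of weakly expressed transcripts is argued against by genes with a mean FPKM of 1 to 20 only. Their median log2 change was 0.0644, against 1.16 for the 7 tested members of the neutrophil list. The 80 tested olfactory and vomeronasal receptor genes go the other way, with a median of 0.581 (0.0882 over the 1320 above 0). Both the 1.16 and the 0.581 cover genes past a filter that favours those high in DSS. With weaker genes included the comparison was closer, at 0.145 for genes above 0 with a mean FPKM under 20 and 0.465 for all 13 list members, so for the weak members such a rise stays open. RNA from neutrophils in the DSS libraries is a candidate explanation, examined with 29 transcripts listed as neutrophil, outside the fixed list and above 0. Of these, 8 had all 3 DSS libraries above all 3 control libraries and 1 had them below. The one-sided exact binomial p was 6.49e-05 against 5% by chance, too small where such transcripts vary together. Of all 12187 tested genes, 774 had all DSS libraries above. That share covers genes past the filter, whereas the 29 were counted with no filter, so the 2 are not like for like. Among the 8 were weak transcripts such as Ifitm6 (mean FPKM 0 in control and 0.384 in DSS) and Csf3 (0.582 and 1.455). Among the 11 of the 29 with a control mean FPKM of at least 1, the counts above and below were 5 and 1 (one-sided exact binomial p = 1.12e-04, with the same limit). These counts cannot tell neutrophil RNA from that of macrophages, monocytes or epithelial cells, whose lists rose too (medians 0.93 and 0.84). Csf3r and Mmp9 of the fixed list overlapped between the groups. S100a9, the most abundant of the list, reached 40.8 FPKM, Lcn2 4.96 and Tyrobp 24.1, and Tyrobp, Fcer1g, Hdc and Mxd1 were also above 10 FPKM in control. Expression of these genes by ILC2s was not tested and stays open.

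The fall of Il5 by 2.43 on the log2 scale is hard to place in a lower share of ILC2 RNA alone, since the ILC2 identity list had a median of −0.506, which lay 1.93 above Il5, whose standard error was 0.191. For the fall of the identity list itself a lower ILC2 share stays open: the neutrophil, macrophage and epithelial lists rose, with medians of 1.16, 0.93 and 0.84, but the T cell and stromal lists, at −0.11 and −0.02, did not, and the spread of these differences was not measured. A trend with gene length or expression level is argued against by the 200 genes nearest to Il5, with a median of −0.0704. A response of ILC2s to DSS, or a change in which ILC2s were sorted, may remain, and neither was tested.

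DSS replicate 1 stood apart from DSS replicates 2 and 3, and 413 genes passed without it. GC content may be set aside as the main cause, since a smooth curve on it held 5.87% of the variance of the log2 difference. Median-of-ratios scaling removed 6.25% of the mean squared difference of 0.641. A factor per library mainly moves the mean of the difference, whose SD over genes was 0.744. The bound for scaling by a few abundant genes as the cause was thus out of reach, and this test carries no weight against it. The SD was 0.775 after scaling, so the gene-to-gene part of the difference remained. The scaling test replaced an earlier one, which counted changed genes and so did not measure this difference; its bound is that of the GC test and was applied when the difference was known. Scaling did move the median difference from −0.340 to −0.063, and this library had 12.49% ribosomal protein fragments, so a part of the difference stays open to it. Gene length held 11.1%, between the bounds set for and against it, so it cannot be told apart from other causes. Whether the animals behind this library differed in disease was not tested.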
